A study of Mus musculus and Homo sapiens with 12 samples.

How the data were processed

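The series holds single-end poly(A) RNA sequencing of EMT6, a mouse mammary carcinoma line, and MDA-MB-231, a human breast adenocarcinoma line. Each line was profiled as wild type and after deletion of PFKFB4, with 3 libraries per group and 12 in all. Per the labels' protocols, both lines grew in high-glucose medium with serum, total RNA was purified on miRNeasy columns, and libraries were made with the Roche mRNA HyperPrep kit. The labels call the libraries biological replicates and do not say whether they came from separate cultures or clones, so p-values measure the spread between these libraries.

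Per the submitters' processing notes, the tools were CASAVA 1.8.2, TopHat2 2.1.1, featureCounts and Subread 1.6.4, with the builds mm10 and GRCh38.p7. Their settings, including strand, are not given in the sources used here. The authors deposited TPM, transcript abundance corrected for length and scaled so that each library sums to 1000000, in 1 table per line. The knockout columns carry the codes A7 in EMT6 and G2 in MDA-MB-231, which no label explains. They were taken as the knockout libraries by elimination, because the other 3 columns of each table are named as wild type.

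Low TPM values were examined for steps left by whole reads. In EMT6, only 43.4 to 44.3% of values of 0.5 to 20 reads came out whole within 0.02 of a read, under an effective length of the exon length minus 249 nt, for genes with over 600 nt of exons. Whole reads were therefore not recovered and no count test was run. The most frequent ratio of low values gives an approximate relative depth. Against wild-type replicate 1 it was 0.779 to 0.95 for the other EMT6 libraries and 1.21 to 1.78 for the other MDA-MB-231 libraries. The number of reads behind a value is not known.

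Mouse gene names, positions and exon lengths came from GENCODE M21 on GRCm38, the assembly that mm10 names. Of 54331 mouse identifiers, 54097 had a symbol, and 12 of the tested genes had no exon length. The files do not pair the 60233 human identifiers with names and no human table was used, so human gene lists, the human PFKFB4 transcript, the overlap between lines and the difference between lines were not analysed here.

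Differential expression was tested within each line with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(TPM + 1) and with no covariate. The design fixed before the data were examined assumed counts and named this test for normalized values. Genes needed at least 0.5 TPM in at least 3 of the 6 libraries. This filter was set once the unit was known and before any test was run. Adjusted p is Benjamini-Hochberg, with calls at 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Means of TPM are given ± SD.

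For EMT6, 36 gene lists fixed before the data were examined were compared with all other tested genes by camera, with a preset correlation between genes of 0.01 and at least 5 tested members. 34 lists qualified. Named genes followed a rule fixed at the same time: the PFKFB family, then the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 TPM in the higher group, no overlap between groups and an established symbol, then up to 2 members per list and direction with the smallest adjusted p. In the human table the symbol criterion could not be applied, and 2 identifiers per direction are given. A few further list members, chosen after their values were seen, are marked as such. Some genes that the rule selects are not reported here.

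Tests were run on simulated data with 200 changed genes per line, 50 at each fold change. In EMT6, on 13499 genes, 62% of genes changed 1.5-fold were recovered, 86% at 2-fold, 98% at 4-fold and 96% at 8-fold, with 8 false calls among 179. In MDA-MB-231, on 15299 genes, the shares were 22%, 52%, 96% and 90%, with 4 false calls among 134. The shares hold only for the genes chosen to be changed in the simulation, and were not split by expression level. They do not give the recovery of low genes or of all tested genes. Calls in the data were far more numerous, 7659 in EMT6 and 3065 in MDA-MB-231. The false calls in the simulation therefore give no error rate for the data.

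Alternatives fixed in advance were limma without a trend, scaling each library by its median ratio to the geometric mean, no filter, a filter of at least 1 TPM, a pseudocount of 0.1, leaving out each library, the replicate number as a block, a minimum change of 2-fold, and an estimated correlation for the lists. Scaling by library total alone equals the deposited TPM. Alternatives chosen after seeing the data were removal of the exon length trend, omission of genes with under 300 nt of exons, omission of the 10 most abundant genes, and the scaling and filter settings for the lists. The length trend was removed by subtracting, in each library, a lowess curve of the deviation from the gene mean on log2 exon length, fitted on protein-coding genes. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.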

Results

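RNA from wild-type and PFKFB4-knockout cells of EMT6 and MDA-MB-231 was compared to ask which transcripts differ after deletion of PFKFB4. This bifunctional enzyme sets the level of a regulatory fructose bisphosphate that acts on glycolysis. Each line had 3 wild-type and 3 knockout libraries, given as TPM. Genes with at least 1 TPM numbered 12350 to 12426 in the EMT6 wild-type libraries and 11871 to 12015 in the knockout libraries. In MDA-MB-231 they numbered 13423 to 13593 and 13038 to 13338. No pair of libraries held more than 0.0086% identical values above 0. Within groups, the SD of the log2 difference between libraries over tested genes was 0.42 to 0.44 in EMT6 and 0.41 to 0.52 in MDA-MB-231, against 0.62 to 0.71 and 0.61 to 0.68 between groups.

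In EMT6 the transcript of the targeted gene was reduced but still present. Pfkfb4 (ENSMUSG00000025648, chromosome 9, 108991778 to 109032228 on GRCm38) stood at 10.4 ± 0.178 TPM in wild type and 7.36 ± 0.763 TPM in the knockout (SD, n = 3 each), with 10.2, 10.5 and 10.4 TPM in the wild-type libraries and 6.96, 6.87 and 8.24 TPM in the knockout libraries. Its log2 fold change was -0.45 ± 0.08 (SE; limma adjusted p = 0.00487). Under median-ratio scaling it was -0.25 (adjusted p = 0.0533), and with the length trend removed -0.18 (adjusted p = 0.124). The labels do not say which part of the gene was edited, so a gene-level value does not test the deletion itself. Among the paralogous enzymes, Pfkfb1 (-0.45, adjusted p = 0.00875) and Pfkfb2 (-0.65, adjusted p = 0.0095) were lower, and both lost their calls with the length trend removed. Pfkfb3 had 6.18 TPM in wild type and 5.8 TPM in the knockout (log2 fold change -0.08, adjusted p = 0.457). Its sign turned under median-ratio scaling (0.11, adjusted p = 0.294) and with the length trend removed (0.28, adjusted p = 0.034), where it was called higher.

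Fabp4, a fatty acid-binding protein (chromosome 3, 10204088 to 10208576), rose from 0.0745 ± 0.0391 to 49.9 ± 3.56 TPM (SD, n = 3), a log2 fold change of 5.56 ± 0.08 (SE; limma adjusted p = 2.96e-06). The interferon-response genes Ifi27l2a (3.97), Usp18 (3.798), Rtp4 (3.65), Irf7 (3.36) and Oasl2 (2.59) rose with it. Tfpi, an inhibitor of coagulation (3.34), the chemokine Ccl7 (3.08), the adhesion molecule Cntn1 (3.04) and the small nuclear RNA Rnu1a1 (2.76) completed the 10 largest. Serpinf1, a secreted serpin (chromosome 11, 75409769 to 75422701), fell from 74.7 ± 2.9 to 0.859 ± 0.363 TPM, a log2 fold change of -5.36 ± 0.14 (SE; adjusted p = 1.44e-05). Padi4, a protein-arginine deiminase (-4.48), Col3a1 (-4.19), Col6a3 (-3.86), Lgals7 (-3.35), U90926 (-3.27), the crystallin Cryaa (-3.18), Eya2 (-3.16) and Col6a2 (-2.95) fell too. Mir7005 (-4.69) also passed the test. Its annotated exon has 69 nt and that of Rnu1a1 has 164 nt. Mir7005 varied widely among wild-type libraries (66.5 ± 38.6 TPM), as did Rnu1a1 (16.7 ± 10.9 TPM) and Lgals7 (11.1 ± 6.12 TPM).

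**Figure D1:**
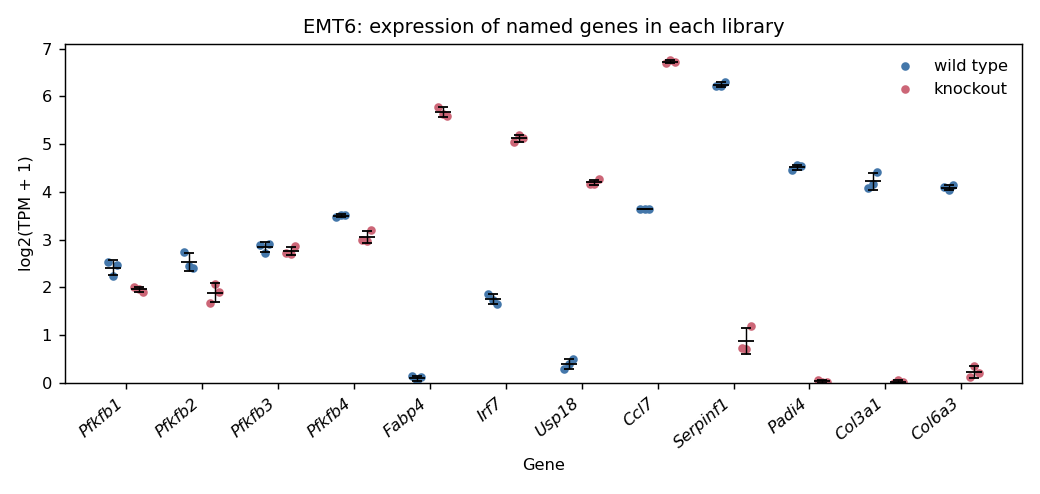
Expression of 12 named genes in EMT6, as log2(TPM + 1) on the vertical axis, with 1 point per library (3 wild type, 3 knockout) and bars for the mean and SD of the 3 libraries. The Pfkfb4 points of the knockout lie below those of the wild type and well above 0, whereas Fabp4 and Serpinf1 change by 5.56 and -5.36.

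Interferon-stimulated genes rose together in the EMT6 knockout. Of 33 tested members, 30 were higher and 1 was lower, with the same counts adjusted over the list alone, and the median log2 fold change was 1.42 (camera adjusted p = 2.64e-25; adjusted p = 0.00914 with an estimated correlation). It was the only list called with an estimated correlation. Usp18, a negative regulator of interferon signalling, rose from 0.322 ± 0.0972 to 17.4 ± 0.695 TPM, and Irf7, a transcription factor of the interferon response, from 2.38 ± 0.245 to 33.8 ± 1.65 TPM (SD, n = 3). Irf1, also a transcription factor, was lower (-0.48, adjusted p = 0.00256). Chosen after their values were seen, Isg15 (2.45) and Bst2 (2.24) were among the more abundant members that rose. Under median-ratio scaling and with the length trend removed, 32 members were higher and 1 lower. The leukocyte markers Cd68 (23.9 to 56.1 TPM) and Coro1a (2.17 to 5.14 TPM) rose with the list.

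Class I antigen presentation genes moved in both directions, with 9 higher and 4 lower of 17, the same counts adjusted over the list alone, and a median of 0.26 (camera adjusted p = 0.00475; adjusted p = 0.493 with an estimated correlation). B2m, the invariant light chain (0.87, adjusted p = 0.00019), and the heavy chain gene H2-D1 (0.84, adjusted p = 0.000165) rose. Tapbp (-0.90) and Tap2 (-0.79), which serve peptide loading, fell. Median-ratio scaling gave 12 higher and 3 lower (median 0.39), and removal of the length trend 10 and 3 (median 0.30). Tapbp and Tap2 lie on chromosome 17, in a stretch where most neighbouring genes were also lower.

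Matrix, adhesion and developmental signalling genes fell. Of 28 collagen and matrix genes, 25 were lower and 2 higher over all genes tested, and 26 and 2 adjusted over the list alone, with a median of -0.74 (camera adjusted p = 8.93e-06; adjusted p = 0.493 with an estimated correlation). Col6a3 fell from 16.03 ± 0.568 to 0.173 ± 0.102 TPM and Col6a2 from 18.8 ± 1.011 to 1.56 ± 0.0526 TPM. Lama4, a laminin chain gene, rose (2.58, adjusted p = 4.32e-05). Median-ratio scaling gave 21 lower and 2 higher (median -0.52), and removal of the length trend 20 and 2 (median -0.41).

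Of 20 integrins and adhesion receptors, 14 were lower and 1 higher (15 and 2 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 0.0069; adjusted p = 0.493 with an estimated correlation). Median-ratio scaling gave 12 lower and 3 higher (median -0.49), and removal of the length trend 13 and 3 (median -0.34). Itgb3 (-2.19) and Ncam1 (-1.23) fell, and Itgav (0.24, adjusted p = 0.0172) rose. Itgav lost its call without wild-type replicate 2, knockout replicate 1 or knockout replicate 2 (adjusted p = 0.0559, 0.0548 and 0.0527). Its log2 fold changes in these smaller fits were 0.23, 0.20 and 0.23. All 10 tested Wnt and Notch genes were lower, also adjusted over the list alone, with a median of -0.94 (camera adjusted p = 0.00212; adjusted p = 0.233 with an estimated correlation). Wnt7b (-1.86), a ligand, and Notch2 (-1.20), a receptor, had the smallest adjusted p. All 10 were lower under median-ratio scaling (median -0.77), and with the length trend removed 8 were lower and 0 higher (median -0.78).

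Nuclear genes of the respiratory chain and cytosolic ribosomal protein genes rose. Of 40 oxidative phosphorylation genes, 30 were higher and 3 lower, with the same counts adjusted over the list alone, and the median was 0.32 (camera adjusted p = 4.77e-12; adjusted p = 0.493 with an estimated correlation). Ndufa1 rose from 95.9 ± 2.05 to 163 ± 5.59 TPM and Uqcrh from 287 ± 11.4 to 447 ± 10.7 TPM (SD, n = 3). Atp5f1 (-0.20) and Ndufb10 (-0.27) were lower in TPM. Under median-ratio scaling Atp5f1 was at 0.02 (adjusted p = 0.633) and Ndufb10 at -0.05 (adjusted p = 0.531). With the length trend removed, Ndufb10 stayed called lower at -0.43, and Atp5f1 was at 0.02 (adjusted p = 0.697). Of 45 ribosomal protein genes, 25 were higher and 3 lower (27 and 3 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 3.82e-09; adjusted p = 0.493 with an estimated correlation). The number higher fell to 15 with no filter and to 18 with a replicate block, with 3 lower in both. Rps6 (0.47) and Rps23 (0.42) rose, and Rpl12 (-0.36) and Rpl5 (-0.34) were lower in TPM but not called under median-ratio scaling. Median-ratio scaling gave 34 respiratory genes higher and 0 lower (median 0.54), and 39 ribosomal genes higher and 1 lower (median 0.40). With the length trend removed, 27 respiratory genes were higher and 1 lower, and 23 ribosomal genes were higher and 5 lower.

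Of 30 autophagy and lysosome genes, 14 were higher and 8 lower, the same adjusted over the list alone, with a median of 0.23 (camera adjusted p = 5.86e-05; adjusted p = 0.123 with an estimated correlation). Median-ratio scaling gave 18 higher and 4 lower (median 0.45), and removal of the length trend 20 and 1 (median 0.44). Map1lc3b, an autophagosome protein (0.91), and Atp6v0d1, a proton pump subunit (0.80), rose. Atg9a (-0.67) and Tfe3 (-0.42) were lower, and Tfe3 was at -0.02 with the length trend removed (adjusted p = 0.77). The 13 mitochondrially encoded transcripts were not called as a list (camera adjusted p = 0.0722), although 10 were lower and 1 higher, the same adjusted over the list alone. The list was called lower under median-ratio scaling (adjusted p = 0.0156), with the length trend removed (adjusted p = 0.0012), with no filter (adjusted p = 0.00492) and without knockout replicate 2 (adjusted p = 0.0443), but not in TPM with an estimated correlation (adjusted p = 0.737) or without genes under 300 nt (adjusted p = 0.18). Mitochondrial transcripts held 9.36 to 12.3% of TPM in the wild-type libraries and 4.98 to 6.39% in the knockout libraries, of which the short gene mt-Atp8 alone held 6.07 to 8.61% and 3.13 to 4.14%, while the short RNA gene Mir6236 held 2.81 to 3.23% and 5.49 to 7.13%. mt-Nd4l fell from 5279 ± 567 to 1680 ± 180 TPM and mt-Nd5 from 889.9 ± 74.3 to 332.5 ± 39.1 TPM, whereas mt-Co3 rose from 1840 ± 137 to 2904 ± 214 TPM. The annotated exon of mt-Nd4l has 297 nt, so it is among the genes omitted under 300 nt.

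Hypoxia-response genes fell, with 15 lower and 2 higher of 21 (16 and 2 adjusted over the list alone) and a median of -0.75 (camera adjusted p = 0.0153; adjusted p = 0.493 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, fell from 5.7 ± 0.0489 to 0.0741 ± 0.0212 TPM, and Loxl2, a matrix cross-linking oxidase, from 5.49 ± 0.0541 to 0.564 ± 0.044 TPM. Adm (1.66) and Fam162a (0.45) rose. Median-ratio scaling gave 12 list members lower and 3 higher, and removal of the length trend 14 and 4, both with a median of -0.54. Of 21 endoplasmic reticulum chaperone genes, 16 were lower and 0 higher over all genes tested, and 17 and 1 adjusted over the list alone, with a median of -0.48 (camera adjusted p = 0.00401; adjusted p = 0.493 with an estimated correlation). Median-ratio scaling gave 16 lower and 3 higher (median -0.26), and removal of the length trend 15 and 1 (median -0.35). Syvn1 (-0.998) and Hspa5 (-0.60) had the smallest adjusted p. Of 18 fatty acid synthesis genes, 12 were lower and 1 higher (13 and 1 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 0.0401; adjusted p = 0.577 with an estimated correlation). Median-ratio scaling gave 11 lower and 3 higher (median -0.42), and removal of the length trend 10 and 3 (median -0.30). Scd2 (-1.05) and Fads1 (-0.67), both desaturases, fell, and Acsl1 (0.45) rose. This list's call was lost with the length trend removed (adjusted p = 0.0971), without genes under 300 nt (0.0513), without a mean-variance trend (0.053), with a replicate block (0.0596) and without knockout replicate 3 (0.0583).

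Glycolysis, the pathway that PFKFB4 acts on, was not called as a list (camera adjusted p = 0.57), with 2 higher and 9 lower of 21, the same adjusted over the list alone, and a median of -0.11. Its median was 0.11 under median-ratio scaling, where 9 members were higher and 6 lower. Pgk1 (0.30) and Hk2 (0.34) rose, while the lactate transporter Slc16a3 (-0.72) and the glucose transporter Slc2a1 (-0.60) fell, with the same signs under that scaling. In the pentose phosphate pathway (camera adjusted p = 0.261), 3 of 10 genes were higher and 2 lower, and 4 and 3 adjusted over the list alone. Pgls (0.71) and Taldo1 (0.46) rose, and H6pd (-1.12) and G6pdx (-0.37) fell.

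The other lists were not called by camera. Adjusted p was 0.055 for G2/M mitosis genes, 0.0699 for purine and pyrimidine synthesis, 0.0857 for G1/S replication genes, 0.151 for the amino acid response, 0.165 for epithelial genes, 0.17 for ribosome biogenesis and 0.187 for angiogenic and growth factors. It was 0.261 for YAP and SRF targets, 0.297 for the citric acid cycle, 0.398 for actin cytoskeleton and migration, 0.503 for both heat shock and cholesterol synthesis, 0.584 for p53 targets and 0.612 for cytokines and chemokines. It was 0.653 for TGF-beta targets, 0.682 for matrix proteases, 0.706 for RAS-ERK feedback, 0.83 for mesenchymal genes, 0.837 for FOXO targets and 0.921 for the antioxidant response. Median-ratio scaling called purine and pyrimidine synthesis (adjusted p = 0.0159), G1/S replication (0.0159) and ribosome biogenesis (0.00768) higher, as did removal of the length trend (0.00537, 0.00386 and 0.0203), against adjusted p = 0.493 for each with an estimated correlation in TPM. With no filter, G2/M mitosis (adjusted p = 0.00021), the amino acid response (0.0157), YAP and SRF targets (0.0214) and actin cytoskeleton and migration (0.0291) were called lower, against 0.493, 0.493, 0.557 and 0.841 with an estimated correlation in TPM. G2/M mitosis was also called lower without wild-type replicate 1 (adjusted p = 0.0435), wild-type replicate 2 (0.0455) or knockout replicate 1 (0.0418). Purine and pyrimidine synthesis was called higher without wild-type replicate 1 (adjusted p = 0.0435) or knockout replicate 1 (0.0453). For ribosome biogenesis, heat shock and p53 targets, the median in TPM was negative but above that of all tested genes, and the test pointed higher. Mesenchymal genes (median -0.29) and the antioxidant response (-0.31) lay below that median while the test pointed higher. Purine and pyrimidine synthesis, the pentose phosphate pathway, G1/S replication and the citric acid cycle had a positive median and a negative mean.

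Single genes changed strongly within lists that were not called. In the cytokine list, with 6 higher and 15 lower of 24, the same adjusted over the list alone, Ccl2 (1.68) and Ccl7 rose, and Cxcl3 (-3.20) and Cxcl2 (-2.33) fell. Among 6 epithelial genes, 1 was higher and 4 lower, the same adjusted over the list alone, and Krt14 fell from 36.5 ± 1.25 to 3.94 ± 0.275 TPM and Krt19 by 1.53 on the log2 scale. The matrix protease Mmp2 (0.91) and the growth factor Gas6 (1.54) rose, while Plau (-1.001), Tagln (-2.32), Tgfb3 (-1.37) and Cthrc1 (-1.56) fell. Of the 20 leukocyte markers, 17 had a knockout mean under 1 TPM. The log2 fold changes of Cd68 and Coro1a were 1.20 and 0.95, and Cd14 stood at 25.3 and 23.7 TPM. Of 15 endothelial markers, 14 had a knockout mean under 1 TPM. With 4 and 1 members past the filter, neither of these lists was tested in the main fit. With no filter, 14 leukocyte markers pointed higher (camera adjusted p = 0.0525), with 4 called higher and 1 lower. For 10 endothelial markers, adjusted p was 0.925.

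**Figure D2:**
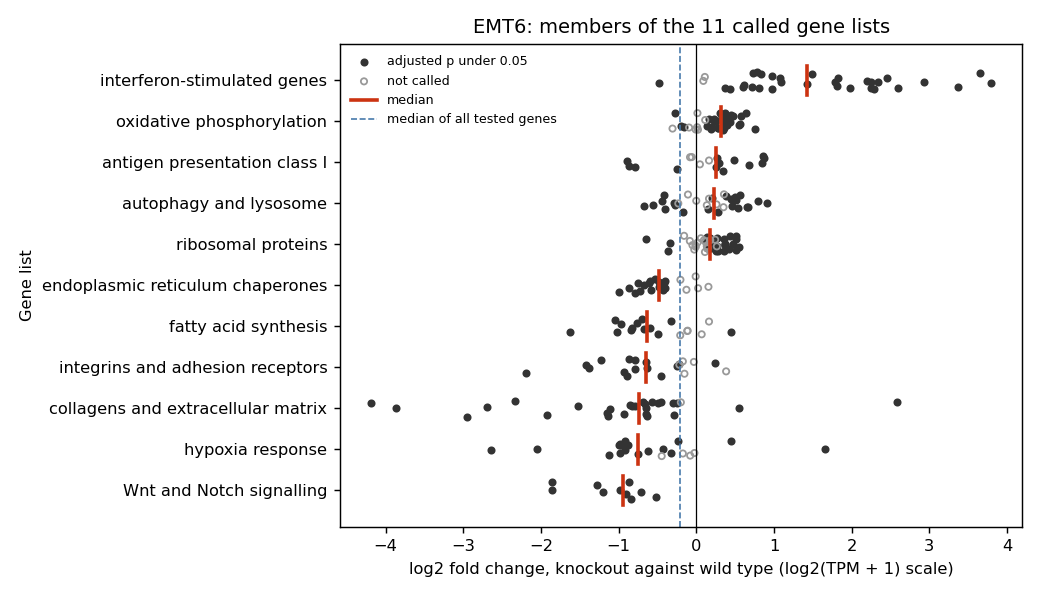
Log2 fold changes (horizontal axis, log2(TPM + 1) scale) of the members of the 11 called lists in EMT6, 1 row of points per list, with filled points for called genes, a bar at the list's median and a dashed line at the median of all tested genes, -0.21. Interferon-stimulated genes have a median of 1.42 and the other lists lie between -0.94 and 0.32.

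Over all 13499 tested genes in EMT6, limma called 1954 higher and 5705 lower, of which 202 and 621 changed at least 2-fold. Groups did not overlap for 66.2% of tested genes, against 10% by chance. The balance of directions followed the scaling. The median log2 fold change of all tested genes was -0.21 in TPM and -0.03 after median-ratio scaling, which called 3427 higher and 3553 lower (49.1% of calls higher, against 25.5% in TPM). Fold changes also followed exon length, with a median of 0.15 in the shortest decile of protein-coding genes (median exon length 1278 nt) and -0.47 in the longest (12421 nt). The longest decile lay 0.53 to 0.70 below the shortest in each knockout library relative to the wild-type mean, and from 0.08 below to 0.15 above it in the wild-type libraries. With this trend removed, 3104 genes were higher and 3682 lower.

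**Figure D3:**
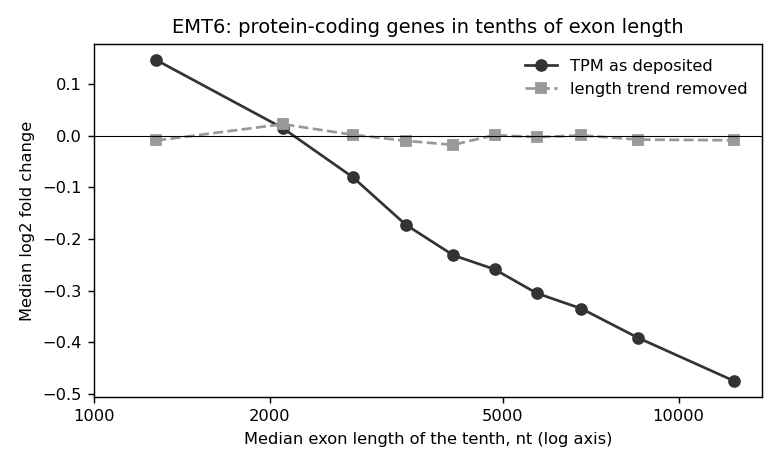
Median log2 fold change of EMT6 protein-coding genes (vertical axis) in deciles of exon length (horizontal axis, nt, log scale), from TPM as deposited and with the length trend removed. The deposited values run from 0.15 in the shortest decile to -0.47 in the longest.

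Fold changes in EMT6 also differed by chromosomal position. With the length trend removed, 300 neighbouring protein-coding genes on chromosome 17 (3114972 to 35062095) had a median of -0.48, and 88.7% of them lay below 0. A group of 150 genes on chromosome 4 (81278500 to 120570276) had a median of 0.29, and 80.7% of them lay above 0. A group of 100 genes on chromosome 3 (101576219 to 122926184) had a median of -0.39. Smaller shifts were found in 150 genes on chromosome 19 (6094419 to 32667187, median -0.23) and 100 on chromosome 8 (106883890 to 124345722, median 0.25). A second group of 150 genes on chromosome 4 (127077383 to 139378730) had a median of 0.24. Cryaa, Tapbp, Tap2, Ndufb10 and the cell cycle inhibitor gene Cdkn1a (-0.74) lie in the chromosome 17 stretch. Uqcrh, Rps6 and Slc2a1 lie in the first stretch on chromosome 4, and Atp5f1 in that on chromosome 3. Fads1 lies in the chromosome 19 stretch and Map1lc3b in that on chromosome 8. Gas6 lies in a single shifted window on chromosome 8 (3122061 to 13890281, median 0.27). Slc2a1 (-0.43 with the length trend removed) and Atp5f1 (0.02) did not share the direction of their stretches.

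**Figure D4:**
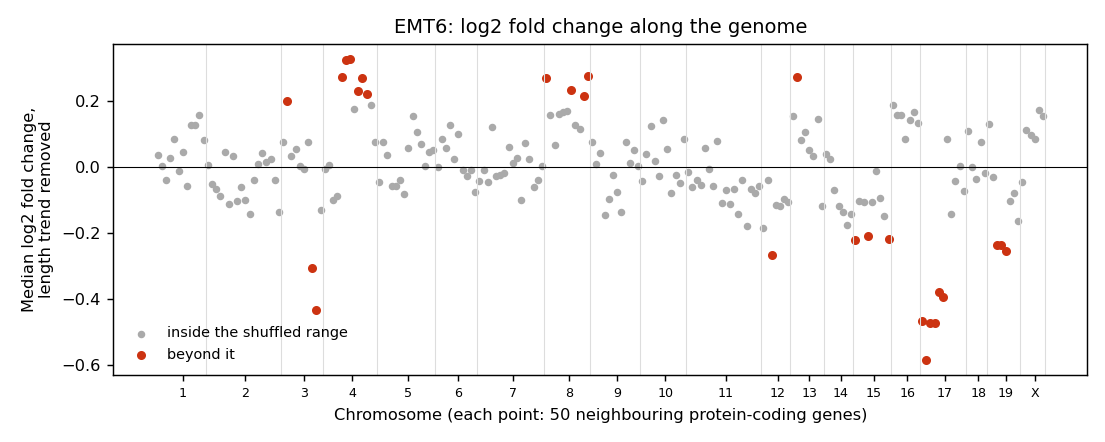
Median log2 fold change with the length trend removed (vertical axis) in 213 windows of 50 neighbouring protein-coding genes in EMT6, ordered by chromosome (horizontal axis). Coloured points are the 27 windows beyond the range of shuffled gene orders, 6 of them on chromosome 17 between -0.58 and -0.38.

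In MDA-MB-231, 15299 genes were tested and limma called 1220 higher and 1845 lower in the knockout, of which 116 and 427 changed at least 2-fold. The files do not pair these identifiers with gene names. By the rule for named genes, ENSG00000101210 rose from 5.92 ± 1.14 to 76.9 ± 2.41 TPM (log2 fold change 3.50 ± 0.13 SE; adjusted p = 4.49e-05), and ENSG00000152137 from 0.225 ± 0.0455 to 11.1 ± 0.694 TPM (3.30 ± 0.10; adjusted p = 2.88e-05). ENSG00000227234 fell from 1012 ± 31.2 to 5.86 ± 0.696 TPM (-7.21 ± 0.09; adjusted p = 4.46e-07), and ENSG00000196611 from 142 ± 12.7 to 0.167 ± 0.134 TPM (-6.94 ± 0.12; adjusted p = 2.48e-06). Groups did not overlap for 40.1% of tested genes, against 10% by chance. The median of all tested genes was -0.04, and -0.01 after median-ratio scaling, which called 1498 higher and 1804 lower. The counts fell when libraries were left out, to 515 higher and 708 lower without wild-type replicate 1, 704 and 922 without wild-type replicate 3, 518 and 1035 without knockout replicate 2, 539 and 1270 without knockout replicate 3, and 802 and 1312 without wild-type replicate 2. By relative depth, the knockout libraries (1.35 to 1.78) were deeper than the wild-type libraries (1 to 1.32). The PFKFB4 transcript was not checked in this line, and whether its effects differ from those in EMT6 was not tested.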

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

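The length trend, the omission of short or abundant genes, and scaling and filter settings for the lists were tried after seeing the data. In EMT6 the numbers of genes higher and lower, 1954 and 5705, became 202 and 621 with a minimum change of 2-fold, 3427 and 3553 under median-ratio scaling, and 3104 and 3682 with the length trend removed; the other alternatives, leaving out each library included, stayed within 1.5 times. In MDA-MB-231, 1220 and 1845 became 116 and 427 with the 2-fold minimum. Leaving out each library gave 515 to 1071 higher and 708 to 1458 lower, in fits with fewer samples. The replicate number as a block gave 534 and 1030 in MDA-MB-231, and 1629 and 5022 in EMT6. Same-numbered libraries did not deviate together: their correlations were 0.065, -0.017 and 0.073 in EMT6 and 0.0017, 0.114 and -0.127 in MDA-MB-231, so the numbers were not taken to pair samples. Of the lists, 5 were higher and 6 lower. With an estimated correlation this became 1 and 0, with interferon-stimulated genes left. Median-ratio scaling and removal of the length trend each gave 8 higher, and no filter gave 11 lower. The cause of these changes was not tested.

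Among 145 named EMT6 genes, 124 kept their direction and side of the threshold under every alternative in which they were tested, 103 of them in all alternatives. In all, 22 were left out of at least 1 alternative, such as genes expressed in 1 group that miss the filter once a library of that group is left out. The 4 identifiers of MDA-MB-231 were kept likewise, with 2 of them left out of some alternatives. Of the other 21, Pfkfb3 turned from -0.08 to 0.11 under median-ratio scaling and to 0.28, called higher, with the length trend removed. The rest lost the call somewhere, 10 of them with the length trend removed and 8 under median-ratio scaling, Pfkfb4 in both; Atp5f1 turned to 0.024 and 0.017. Reversals among called genes that are not named were not counted.

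The test turned direction in 7 lists, 0 of them called in TPM and 0 called after turning. Their medians were 0.11 for glycolysis under median-ratio scaling and 0.038 with the length trend removed, 0.0054 for cholesterol synthesis and 0.0019 for FOXO targets with that trend removed, and -0.231 for the antioxidant response with no filter. For mesenchymal genes they were -0.0985 under median-ratio scaling, -0.106 with no filter and -0.0096 with the length trend removed. Leaving out each library gave medians of -0.413 to -0.217 for mesenchymal genes, -0.304 to -0.172 for RAS-ERK feedback, -0.343 to -0.217 for FOXO targets, -0.366 to -0.280 for the antioxidant response and -0.477 to -0.328 for cytokines and chemokines.

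Read depth is not known, so how far it limits low genes cannot be stated. The planned lists for MDA-MB-231, the overlap and the difference between lines and their alternatives were not run, because human names were not used here, and count-based tests were not run on TPM.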

Other observations

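The tests on interferon-stimulated genes, the counts of splits and the tests of the length trend on the other lists were chosen only after those results were seen. The tests of expression level, of long noncoding RNA and of neighbouring genes were written before their outcomes, although the overall length trend and the medians by chromosome had been seen.

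The rise of interferon-stimulated genes in the EMT6 knockout is not accounted for by the length trend. The list's median of 1.42 lay far above the medians of the length deciles, -0.47 to 0.15. Its camera adjusted p was 1.64e-19 once that trend was removed. RNA from leukocytes is argued against too, by 5 of the 20 leukocyte markers. Ptprc, Tyrobp, Laptm5, Lyz2 and Fcer1g, which are abundant in such cells, reached at most 0.584 TPM in any knockout library. Usp18 and Irf7 rose to 17.4 and 33.8 TPM, and Bst2, chosen after its value was seen, to 220.3 TPM. Of the 5 markers, Lyz2 went from 0.0164 to 0.413 TPM, and Tyrobp stayed at 0. The markers Cd68 and Coro1a rose to 56.1 and 5.14 TPM. With no filter, 14 leukocyte markers pointed higher as a list without being called (camera adjusted p = 0.0525). The 33 tested members lie on 14 chromosomes. Loss of PFKFB4 may raise these genes, but the knockout columns carry 1 code, so loss of PFKFB4 cannot be told apart from other differences between the knockout and wild-type cultures.

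A hypothesis for the fall of long genes in EMT6 is a length-dependent bias between libraries. Differences in expression level with length do not account for it, because the rank correlation of log2 fold change with exon length across genes, -0.39 over 11104 protein-coding genes, was -0.24 or stronger within each quintile of mean expression. In 807 long noncoding RNA genes it was -0.13, with a 95% bootstrap interval of -0.20 to -0.05. The interval is wholly negative, so a trend was present in them, but it spans the bound of -0.1 set for the test. These genes were not matched to protein-coding genes for expression level, so the test does not decide on a library bias. The trend may therefore be technical or biological. The subtracted curve was fitted over all expression levels together. The correlation was -0.24 in the lowest quintile of mean expression and -0.45 in the highest. Part of the trend may therefore remain in abundant genes, so calls kept after its removal do not exclude it for the lists below. With the trend removed, camera adjusted p was 2.93e-06 for oxidative phosphorylation (median 0.25, against 0.32 in TPM), on the preset correlation. It was 0.00185 for ribosomal proteins (0.19, against 0.18) and 7.17e-05 for collagens and matrix (-0.41, against -0.74). The fatty acid synthesis list lost its call with the trend removed.

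Neighbouring genes shifted together in EMT6, and a candidate explanation is a copy-number difference between the knockout and wild-type cells. With the length trend removed, 27 of 213 windows of 50 neighbouring protein-coding genes had a median beyond the range that holds all but 0.2% of shuffled windows (-0.21 to 0.19), against at most 4 in 1000 shuffled gene orders. On chromosome 17 the 6 windows up to position 35062095 were beyond it and the following window was at 0.09. The 300 genes of that stretch had medians of -0.47, -0.49 and -0.42 in the 3 knockout libraries, against -0.01 to 0.02 in the wild-type libraries. Coordinated regulation of neighbouring genes was not tested and stays open, as does whether such differences arose with the knockout or with the selection of cells.

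Of the 10 splits of the 6 libraries into 3 and 3, only the real one called as many genes in either line, 1 split of 10 each: 7659 genes in EMT6 against at most 10 in the others, and 3065 in MDA-MB-231 against at most 12. For the lists the real split called 11 and the others 1 to 7, all at the preset correlation. With 10 splits the share cannot fall under 0.1, too few to reach 0.05. Each other split sets 2 libraries of one group and 1 of the other against the rest. Part of the group difference remains in it, and part adds to its spread within groups. Few genes called in the other splits were therefore likely from the start, so the contrast in gene calls decides nothing. Lists were called in those splits all the same, whether or not through the remaining group difference. A list call at the preset correlation therefore does not by itself show a difference between knockout and wild type.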
